A study of Folsomia candida with 12 samples.

How the data were processed

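Whole springtails of the soil species Folsomia candida were kept on cadmium-spiked or untreated reference soil, and RNA was taken after 2, 4 and 7 days. Per the series description, each RNA sample came from 30 animals of 1 jar, and 4 jars of each soil were sampled at each day. Each of the 12 arrays carried the labelled RNA of 1 cadmium jar and 1 reference jar of the same day, so 24 RNA samples were measured. The cadmium RNA carried Cy5 on 2 arrays and Cy3 on the other 2 arrays of each day, per the labels. Labelling started from 500 ng of RNA, per the labels' protocols. The cadmium dose is not given in the sources used here.

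The deposited scanner files hold, per the file headers, spot and local background intensity values read by Feature Extraction 9.1.1.1 for day 2 and 9.1.3.1 for days 4 and 7. The deposited log10 ratio column gives red (Cy5) over green (Cy3) after the scanner software's own background and dye correction, per the file headers. All scanner files except that of day 2 array 1 hold signals rounded to 3 significant digits. The deposited value table holds log2 ratios made by the authors, and the submitters' processing notes name limma 2.9.1. Its scale, centring and direction are not stated with the table. On every array its values followed the ratios computed here with r between -0.999 and -0.994 and a slope between -1.09 and -1.04, so it runs as reference over cadmium. The column medians lay between -0.0103 and 0.00316.

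Each array held 10806 spots, of which 544 were controls, and 5131 probes of 60 bases were each printed on 2 spots. Mean signals were corrected with normexp (offset 50) and the median local background, and normalised within each array by loess with a span of 0.3. Control spots and spots marked as outliers had no weight in the loess, and outlier spots were left out afterwards (0 to 16 per array). Saturated spots (3 to 59 per array) were kept. Ratios were turned to cadmium over reference by the labelled dyes, and the 2 spots of a probe were averaged. Probes well above background in either channel on at least 4 of the 12 arrays were tested, which kept 3994 probes and left out 1137.

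One linear model was fitted over all 12 arrays with limma 3.58.1 in R 4.3.3. It had a coefficient for each day and a dye coefficient, with 8 residual and 1.81 prior degrees of freedom. Moderated tests compared cadmium with reference at each day, averaged over the days, and between pairs of days, and a moderated F test asked for any difference between days. Adjusted p values are Benjamini-Hochberg values over the 3994 probes, with a threshold of 0.05. The dye coefficient passed that threshold for 0 probes. The limma p values measure the spread of ratios between arrays, which mixes differences between jars with technical variation. The number of arrays limits their precision. The Fisher and permutation p values given further below run over probes or over array scores and do not measure the spread between jars.

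Loess assumes that most probes do not differ between the soils at any given intensity, so changes are relative to the bulk of the probes. Normexp with an offset pulls the ratios of dim probes towards 0. For signals of a single RNA, loess-normalised ratios were combined with quantile-normalised average intensities. A fold is given as "at least" where the dimmer RNA was not well above background on any array of the day. Such a bound sets the bright mean against the higher of the dim signal and the lowest signal well above background on each array. It takes no account of the spread between arrays, so it is no confidence limit.

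The same fit was tested on simulated ratios with the measured spread of each of the 3994 probes and 200 probes changed at day 4. For cadmium against reference at day 4, 56.0% of 1.41-fold, 82.0% of 2-fold, 98.0% of 4-fold and 100% of 16-fold changes were recovered. For the effect at day 4 minus day 2, 36.0%, 60.0%, 92.0% and 96.0% of those sizes were recovered. The simulation drew the probes independently. It also drew the arrays independently, with no correlation within slides or scan sessions, so the recovered shares do not allow for such correlation.

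The probes carry cluster numbers beginning with Fcc and no gene name. None of these IDs matched the locus tags, accessions or symbols of the gene table for assembly GCF_002217175.1, and no genome or transcript sequence was used here. Genome positions are therefore not given, and the 29 keyword lists of stress, metal-handling and tissue genes fixed in advance were not run. Probes are given by ID and sequence. The rule took, for each day, the 2 largest rises and the 2 largest falls past the threshold with the same sign on all 4 arrays, as ranked under the main settings. The order by size within a pair of named probes changed under some alternatives, so the probes are not ranked against each other. For each pair of days it took, from the probes called by the F test, at most 2 of the largest differences in each direction; the planned limit of 5 for named genes was lowered to the limit of 2 for unnamed probes.

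The design, the filter, the rule for named probes and the alternatives were chosen before the data were examined. Alternatives covered background correction, normalisation, the probe filter, the dye coefficient, the arrays in the fit, array weights, the variance prior, saturated spots, slide and scan session as blocks, the authors' value table, the threshold, the replicate number as a block, and each array left out. The effect of the 2 scan sessions of day 2 as a coefficient, and the array number as a random block, were added afterwards.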

Results

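The 12 arrays compared springtails on cadmium-spiked soil with springtails on reference soil after 2, 4 and 7 days, with 4 arrays per day and 1 jar of 30 animals behind each RNA. Folsomia candida is a small soil arthropod widely used in soil toxicity testing, and cadmium is a toxic metal. Median spot signals lay between 86.3 and 422 for the cadmium RNA and between 74.95 and 404 for the reference RNA, over a median background of 45 to 54 in green and 70 to 77 in red. Between 59.2% and 92.8% of spots were well above background for the cadmium RNA, and between 57.9% and 78.1% for the reference RNA. The median difference between the 2 spots of a probe was 0.040 to 0.081 on the log2 scale. The brightest arrays were day 2 arrays 1 and 2. Day 2 was scanned in 2 sessions of 2 arrays each, and days 4 and 7 together in another.

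All ratios below are log2 cadmium over reference, the opposite direction to the authors' deposited value table. The direction rests on the dyes given in the labels. If those dyes were exchanged on every array, each higher and lower below would exchange too. Arrays of the same day correlated across the 3994 tested probes with a median r of 0.70 at day 2, 0.53 at day 4 and 0.55 at day 7. Pairs of arrays from different days had a median r of 0.55. The lowest r was -0.26, between day 4 array 2 and day 7 array 4. Probes are not independent replicates, so these values describe the arrays only.

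After 2 days, a group of transcripts was strongly raised on cadmium soil and another was strongly lowered. Probe Fcc00057C1 (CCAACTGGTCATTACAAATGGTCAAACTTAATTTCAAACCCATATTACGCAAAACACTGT) rose by 5.78 ± 0.33 (SD, n = 4), or 54.9-fold, with a limma adjusted p of 0.000109. All its cadmium spots were saturated on 2 of the 4 arrays, so the ratios there are lower limits. With saturated spots left out, the mean was 6.04 over the remaining arrays alone. Fcc00343C3 (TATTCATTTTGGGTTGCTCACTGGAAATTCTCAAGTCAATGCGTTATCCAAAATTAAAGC) rose by 5.66 ± 0.75 (n = 4, adjusted p = 0.000323). Among the falls, Fcc00688C1 (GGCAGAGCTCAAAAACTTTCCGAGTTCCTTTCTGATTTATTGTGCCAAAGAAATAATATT) stood at -5.53 ± 1.88 (n = 4), or 46.4-fold lower, with an adjusted p of 0.000525. Fcc02721 (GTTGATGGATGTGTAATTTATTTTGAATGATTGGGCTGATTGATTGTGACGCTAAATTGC) stood at -5.10 ± 0.80 (n = 4, adjusted p = 0.000367).

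At day 2, 684 of the 3994 probes passed the threshold, 418 of them higher and 266 lower on cadmium soil. Changes of at least 2-fold were found among 163 of the higher and 84 of the lower probes, and of at least 4-fold among 64 and 33. For 27 of the higher probes the reference RNA was not well above background on any of the 4 arrays. The 33 probes that were at least 4-fold lower had a median cadmium signal of 6.43 on the log2 scale, against 10.04 in the reference RNA. The higher share of the calls was 61.1%, 71.8% with median centring in place of loess, 69.1% with scan session as a random block (293 higher, 131 lower) and 77.4% at an adjusted p under 0.01 (223 higher, 65 lower). This share was 75.7% from the day 2 arrays alone (153 higher, 49 lower), but 56.6% with the scan sessions of day 2 as a coefficient (453 higher, 347 lower). The count of 684 was 640 with slide as a random block and 424 with scan session as a random block. It was 368, 328 and 382 without arrays 1, 2 and 3, and 202 from the day 2 arrays alone.

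**Figure D1:**
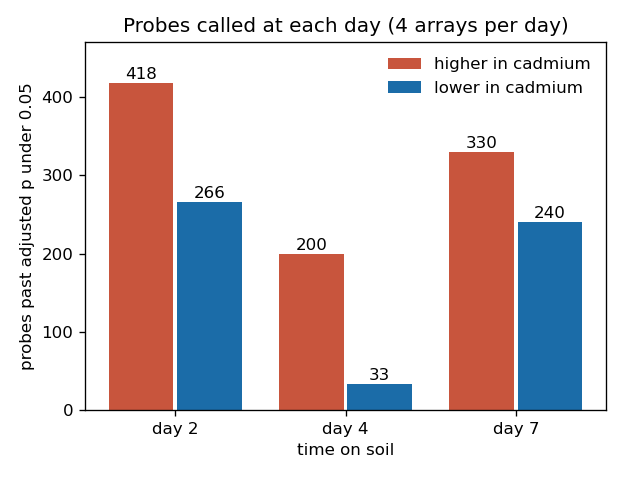
Bars give the number of probes (vertical axis) past an adjusted p of 0.05 at each day (horizontal axis), higher (red) or lower (blue) on cadmium soil, from 4 arrays per day. Day 4 had 200 higher and 33 lower probes, against 418 and 266 at day 2 and 330 and 240 at day 7.

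After 4 days, rises made up most of the called changes. Fcc00057C1 rose by 6.74 ± 0.15 (n = 4), or 107-fold, with an adjusted p of 9.19e-05. Fcc04611 (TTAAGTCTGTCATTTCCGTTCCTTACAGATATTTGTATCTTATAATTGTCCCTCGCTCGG) rose by 6.43 ± 0.95 (n = 4, adjusted p = 0.00186). The falls chosen by the rule were those of Fcc01582 (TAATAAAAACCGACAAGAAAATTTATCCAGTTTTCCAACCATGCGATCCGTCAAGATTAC), at -3.27 ± 1.23 (n = 4, adjusted p = 0.00138), and Fcc00508C1 (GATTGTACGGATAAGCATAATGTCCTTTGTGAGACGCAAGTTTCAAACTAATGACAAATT), at -3.03 ± 1.501 (n = 4, adjusted p = 0.0102). Array 4 gave the lowest value for both falls, at -5.12 and -4.82. The call was lost in 1 of 28 alternative settings for Fcc01582 and in 4 of 28 for Fcc00508C1.

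In all, 200 probes were higher and 33 lower at day 4, so that 85.8% of the 233 calls were rises. At least 2-fold changes numbered 102 rises and 10 falls, and at least 4-fold changes 44 rises and 7 falls. The 44 strong rises had a median of 3.12 at day 4, 2.82 at day 2 and 2.89 at day 7. They were chosen at day 4, which favours larger values there. The count of 233 was 570 with array weights (435 higher, 135 lower) and 176 with slide as a random block (164 higher, 12 lower). It was 66 with scan session as a random block (62 higher, 4 lower) and 130 with median centring (113 higher, 17 lower). The count was 147, 95, 106 and 93 without arrays 1 to 4 in turn, and 66 from the day 4 arrays alone (65 higher, 1 lower).

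After 7 days, both rises and falls were called, and the share of falls rested on the settings. Fcc04611 rose by 6.25 ± 2.61 (n = 4), or 76.0-fold, with an adjusted p of 0.00186, and Fcc00057C1 by 5.997 ± 1.66 (n = 4, adjusted p = 0.000185). Their wide spread came from array 4, which read 2.36 and 3.51, while the other arrays read 7.20 to 7.997 for Fcc04611 and 6.76 to 6.88 for Fcc00057C1. Of the 8 cadmium spots of Fcc00057C1 at day 7, 1 was saturated. The falls chosen by the rule were those of Fcc05266 (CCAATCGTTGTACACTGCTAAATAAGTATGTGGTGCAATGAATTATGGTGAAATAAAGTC), at -4.54 ± 1.03 (n = 4, adjusted p = 0.00260), and Fcc01912C1 (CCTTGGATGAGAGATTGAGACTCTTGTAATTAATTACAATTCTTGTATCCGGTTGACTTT), at -3.90 ± 1.22 (n = 4, adjusted p = 0.00805). The call was lost in 1 of 27 alternative settings for Fcc04611 and in 3 of 27 for Fcc01912C1.

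At day 7, 330 probes were higher and 240 lower. At least 2-fold changes were found in 117 rises and 102 falls, and at least 4-fold changes in 47 and 37. The 37 strong falls had a median of -2.61 at day 7, -1.37 at day 4 and -1.26 at day 2. They were chosen at day 7, which favours larger values there, and the F test called a difference between days for 0 of them. At least 2-fold falls were seen in 30 of the 37 at day 2 and in 30 at day 4. For 45 of the higher probes the reference RNA was not well above background on any array. Over the rises of more than 2-fold on the other 3 arrays, array 4 had a slope of 0.32 against their mean, where the other arrays of day 7 had slopes of 1.08 to 1.25. Without array 4, 336 probes were higher and 118 lower. The count of 570 was 1374 with array weights (706 higher, 668 lower), 422 with slide as a random block and 91 with scan session as a random block. It was 129 without array 1, 130 without array 3, and 89 from the day 7 arrays alone. Rises made up 57.9% of the calls, 68.1% with median centring, 83.5% with scan session as a random block (76 higher, 15 lower) and 80.3% at an adjusted p under 0.01 (106 higher, 26 lower), but 36.0% from the day 7 arrays alone (32 higher, 57 lower).

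**Figure D2:**
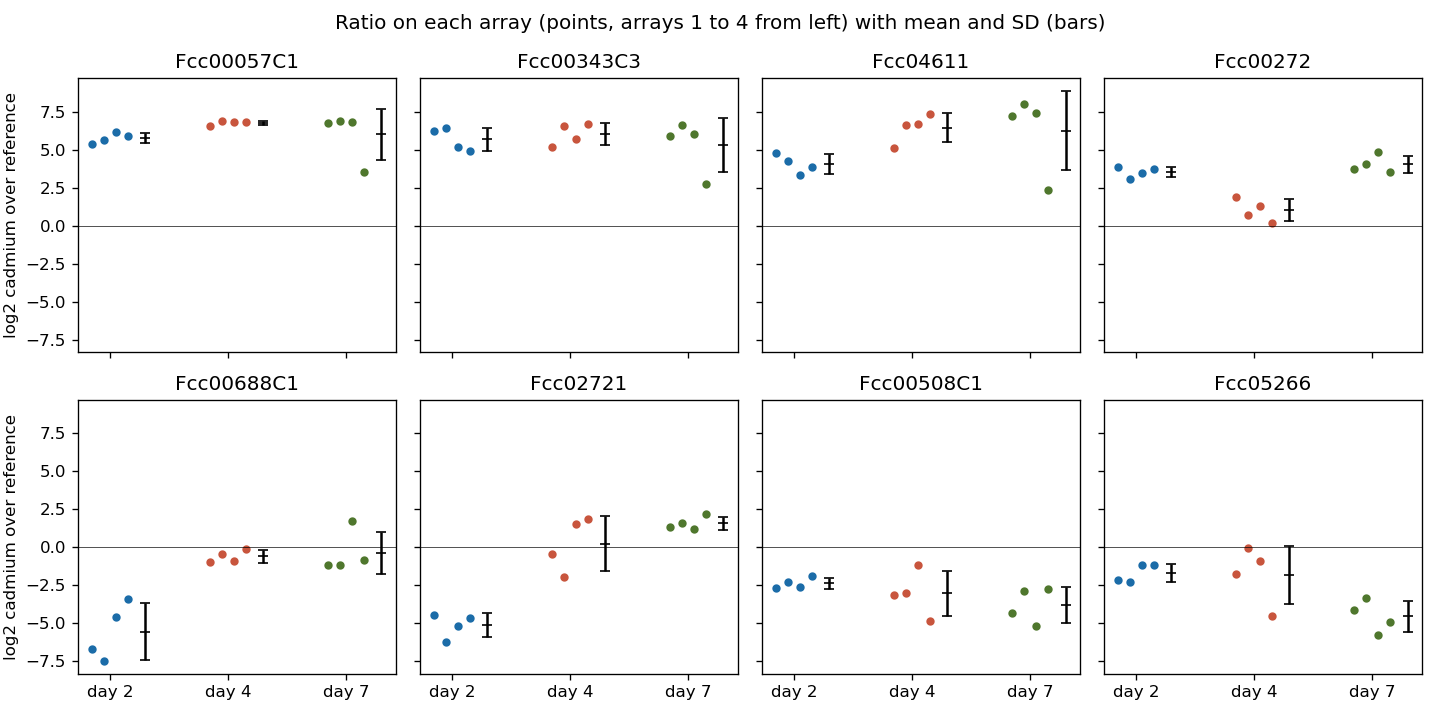
Points give log2 cadmium over reference (vertical axis) on arrays 1 to 4 of each day (horizontal axis) for 8 probes, and bars give the mean and SD of the 4 arrays. Fcc00057C1 stands at 5.78, 6.74 and 5.997 at days 2, 4 and 7, whereas Fcc02721 stands at -5.10, 0.25 and 1.59.

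Averaged over the 3 days, 733 probes were higher and 659 lower on cadmium soil, which is 34.9% of the probes tested. Most of these changes were small, with a median of 0.39 among the higher and -0.36 among the lower probes. At least 4-fold changes were found in 42 higher and 10 lower probes. With scan session as a random block, 594 probes passed the threshold, 407 higher and 187 lower. Falls slightly outnumbered rises with the scan sessions of day 2 as a coefficient, with 749 higher and 755 lower, and without day 2 array 4, with 705 higher and 726 lower.

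Rises were shared between days more often than independent lists of the same sizes would be. Between days 2 and 4, 144 probes were higher at both, where independent lists would share 20.9. Between days 2 and 7 the overlap was 197 against 34.5, and between days 4 and 7 it was 145 against 16.5. For falls, the overlaps were 14 against 2.20, 60 against 16.0 and 20 against 1.98. In all, 118 probes were higher and 9 lower on all 3 days. The 118 had median changes of 2.32-fold, 2.25-fold and 2.15-fold at days 2, 4 and 7. Across the tested probes, the effects correlated with an r of 0.69 between days 2 and 4, 0.69 between days 2 and 7, and 0.78 between days 4 and 7. The days used different jars and arrays, and the fit shared the dye coefficient and the variance estimate.

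Most strong falls at day 2 were within 2-fold of no change at the later days, while most strong rises were still above 2-fold. Of the 33 probes at least 4-fold lower at day 2, 26 were within 2-fold of no change at both later days. The medians of all 33 were -0.24 at day 4 and -0.04 at day 7. Their median cadmium signal was 6.43 at day 2, 9.01 at day 4 and 9.33 at day 7, and their median reference signal 10.04, 9.70 and 9.64. Of the 64 probes at least 4-fold higher at day 2, 49 were still at least 2-fold higher at day 4 and 59 at day 7. Both groups were chosen at day 2, which favours larger values there. The difference between days itself passed the F test for 5 of the 33 and 3 of the 64.

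**Figure D3:**
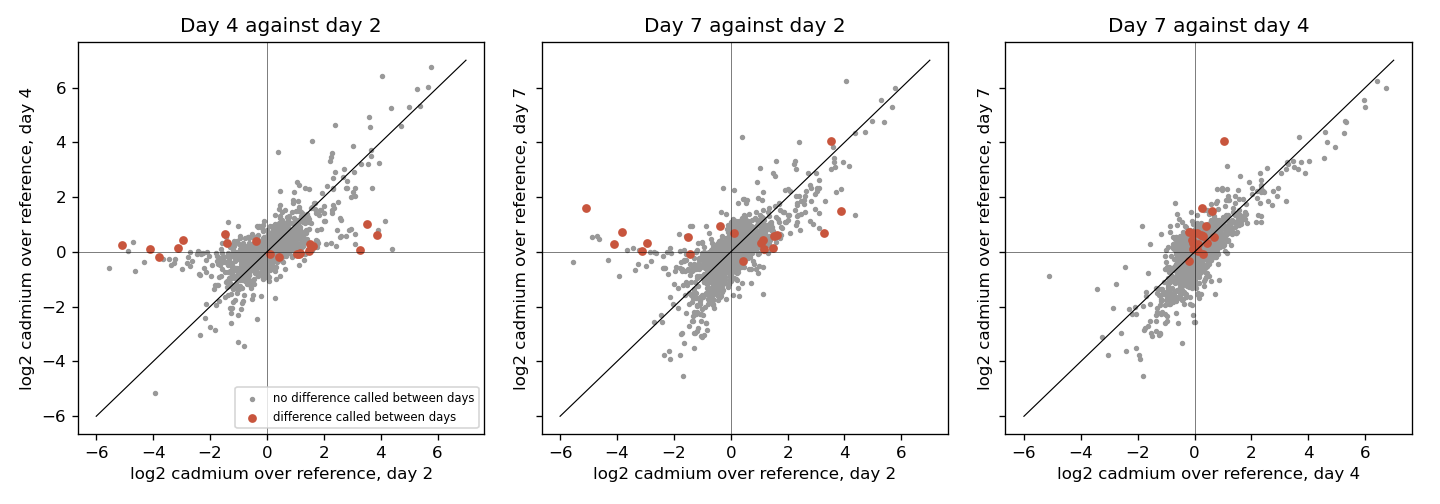
Each point is 1 probe, with log2 cadmium over reference at 1 day on each axis and the line of equality, and red marks the 19 probes whose effect differed between days. Of the 64 probes at least 4-fold higher at day 2, 15 lie within 2-fold of no change at day 4 and 5 at day 7, against 31 and 26 of the 33 at least 4-fold lower.

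The effect of cadmium differed between days for 19 probes by the F test. In 9 of these the effect was highest at day 2 and in 8 it was lowest at day 2. From day 2 to day 4, 32 probes differed, 11 with a higher and 21 with a lower effect at day 4. Fcc02721 changed by 5.35 (SE 0.78, adjusted p = 0.0181), from -5.10 ± 0.80 to 0.25 ± 1.79 (n = 4 each). Fcc00943C1 (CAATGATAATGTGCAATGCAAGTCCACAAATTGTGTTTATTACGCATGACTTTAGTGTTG) changed by 4.23, from -4.11 ± 0.82 to 0.12 ± 0.78 (n = 4 each, adjusted p = 0.00911). In the opposite direction, Fcc00583C1 (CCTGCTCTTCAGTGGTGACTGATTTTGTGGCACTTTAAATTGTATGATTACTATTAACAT) went from 3.86 ± 0.18 to 0.62 ± 0.60 (n = 4 each, adjusted p = 0.00911). Its reference RNA was not well above background on any array of day 4 or day 7, and the bound computed at day 4 was 1.44-fold. That bound shows no rise, since the day 4 effect was not called (limma adjusted p = 0.243). The size of its difference from day 2 is therefore uncertain. Fcc00950 (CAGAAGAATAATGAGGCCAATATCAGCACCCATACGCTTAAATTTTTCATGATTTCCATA) went from 3.29 ± 0.74 to 0.07 ± 0.86 (n = 4 each, adjusted p = 0.0215). The reference RNA of Fcc00950 was well above background on 1 of the 4 arrays of day 4, so the size of its difference is uncertain too. Of the alternative settings, 8 of 30 ended the call for Fcc02721, 3 of 30 for Fcc00943C1, 5 of 29 for Fcc00583C1 and 11 of 29 for Fcc00950.

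From day 2 to day 7, 11 probes differed, 8 with a higher and 3 with a lower effect at day 7. Fcc02721 differed by 6.69 (SE 0.78, adjusted p = 0.00983) and reached 1.59 ± 0.43 at day 7 (n = 4). Fcc05669 (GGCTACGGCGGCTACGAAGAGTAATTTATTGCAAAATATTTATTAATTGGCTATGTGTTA) went from -3.81 ± 0.57 to 0.72 ± 0.40 (n = 4 each, adjusted p = 0.0172). At day 2, 2 of its 8 reference spots were saturated, and the difference of 4.53 was 4.58 with saturated spots left out. Fcc00583C1 went from 3.86 ± 0.18 to 1.49 ± 0.76 (n = 4 each, adjusted p = 0.0450), a rise of at least 2.80-fold at day 7. This last difference rested on the settings, with the call lost in 21 of 29 alternative settings, over which it ran from -2.67 to -0.86. Fcc01171C1 (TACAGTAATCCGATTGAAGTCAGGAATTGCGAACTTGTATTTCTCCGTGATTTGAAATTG) went from 1.47 ± 0.30 to 0.15 ± 0.15 (n = 4 each, adjusted p = 0.00954). At day 7 its cadmium RNA was well above background on 2 of 4 arrays and its reference RNA on 0. The bound of 1.09-fold computed there shows no rise, since the day 7 effect was not called (limma adjusted p = 0.355). The size of this difference is uncertain as well. The call was lost in 3 of 30 settings for Fcc02721, 4 of 30 for Fcc05669 and 5 of 29 for Fcc01171C1.

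From day 4 to day 7, 2 probes differed, both with a higher effect at day 7, but array weights, whose estimation stopped before converging, called 130, of which 42 were higher and 88 lower. Fcc00272 (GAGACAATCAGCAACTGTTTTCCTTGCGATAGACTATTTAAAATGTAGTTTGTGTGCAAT) stood at 1.02 ± 0.74 at day 4 and 4.04 ± 0.56 at day 7 (n = 4 each, adjusted p = 0.0129), after 3.54 ± 0.35 at day 2. Fcc02871C1 (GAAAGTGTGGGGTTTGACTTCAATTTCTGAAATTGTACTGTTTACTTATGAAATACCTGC) stood at -0.06 ± 0.04 and 0.70 ± 0.05 (n = 4 each, adjusted p = 0.0129). The call was lost in 9 of 29 settings for Fcc00272 and in 13 of 30 for Fcc02871C1. At an unadjusted p under 0.05, 219 probes differed between these days. Without day 4 array 2 or 3, or without day 7 array 2, 3 or 4, no probe passed, with 94, 111, 363, 221 and 119 probes at an unadjusted p under 0.05.

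Day 2 was scanned apart from days 4 and 7, so a difference of day 2 from the later days cannot be told apart from a difference of scan session. The version of Feature Extraction differed in the same way. Each day also had its own slides, so a difference between any days, days 4 and 7 included, cannot be told apart from a difference of slides. With scan session as a random block, 1 probe differed between days 2 and 4, 0 between days 2 and 7 (228 at an unadjusted p under 0.05) and 3 by the F test. The fitted differences of the probes named above could not move under this block. Each session held equal numbers of arrays for each of its days and each dye, and day 2 was split evenly. Their adjusted p rose to between 0.0592 and 0.222 for the differences from day 2. Other settings raised the counts: array weights gave 57, 34 and 124 for days 2 and 4, days 2 and 7 and the F test, and the scan sessions of day 2 as a coefficient 60, 46 and 51. Between days 2 and 7, 27 were called both without the dye coefficient and with the trend and robust prior, which gave 36 and 29 by the F test. The counts of 32 and 11 also depended on single arrays. Between days 2 and 4 they were 16, 6 and 5 without day 2 arrays 1, 2 and 3, and 8, 5 and 2 without day 4 arrays 1, 3 and 4. Between days 2 and 7 they were 3, 6, 0 and 23 without day 2 arrays 1 to 4 in turn, 5 without day 7 array 1 and 35 without day 7 array 4. The F test called 2, 5 and 4 probes without day 2 arrays 1, 2 and 3, 10 without day 7 array 1 and 47 without day 7 array 4. From Agilent's processed signals, the calls were 11 higher and 2 lower between days 2 and 4, and 15 higher and 0 lower between days 2 and 7. Between days 2 and 4 the strict filter also gave mostly higher effects, 8 against 2. The numbers were nearly even with an offset of 10, with 10 higher against 9 lower, and without day 7 array 4, with 21 against 18.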

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

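The tests of the day 7 array with dim signals and mixed reference RNA were chosen after its values were seen, as were all tests of the second axis of variation; the other tests were chosen before their results.

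Among 69 sets of 4 arrays tested for a value far from the others, 8 held one, and about 3.45 are expected by chance. On day 7 array 4, Fcc00057C1 read 3.51 and Fcc04611 2.36. On day 4 array 4, Fcc01582 read -5.12 (others -2.77 to -2.52), Fcc01912C1 -4.98 (others -1.16 to -0.39) and Fcc02871C1 -0.118 (others -0.046 to -0.037). Fcc00057C1 read 6.52 on day 4 array 1 (others 6.80 to 6.85), Fcc00583C1 1.51 on day 4 array 2 (others 0.24 to 0.41) and Fcc00688C1 1.70 on day 7 array 3 (others -1.19 to -0.81).

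Day 7 array 4 showed weak rises. Over 106 probes with a rise of 1 to 2 on the log2 scale on the other 3 arrays of that day, its median was 0.19 where theirs was 1.30. Reference RNA of the same array mixed into the cadmium RNA would need a share of 90.4% and would bring falls near -0.09, but 107 probes with a fall of 1 to 2 on the other arrays had a median of -1.43 on array 4 (95% bootstrap interval -1.53 to -1.24). Over all falls of more than 2-fold on the other 3 arrays of the day, array 4 had a slope of 0.65 (152 probes). The slopes of falls were 1.27, 0.53 and 1.02 for arrays 1 to 3. Dim signals are argued against by a slope of rises of 0.35 (SE 0.034) over 87 bright probes. RNA resembling that of a reference jar stays open, since in the cadmium signal of array 4 the falls stood at a median share of 0.36 of the way from the cadmium to the reference level of the other arrays, and the rises at 0.75. No biological explanation was tested, and a jar whose animals responded less may be among the causes.

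A second axis of variation over the 24 RNA samples took 25.6% of the variance, after a first axis (34.9%) on which the cadmium samples scored 1.67 to 31.3 and the reference samples -22.7 to -13.0. The cadmium sample of day 7 array 4 had the score of 1.67. Within the scan session of days 4 and 7, the second-axis scores of the 2 RNAs of an array correlated at r = -0.22 (exact permutation p = 0.593, two-sided, 8 arrays, upper 95% limit of r 0.57; Spearman's rho -0.31, exact permutation p = 0.462; r = -0.55 without the 2 arrays farthest from the median). These values argue against a strong array effect common to both channels there. A weaker common effect, with r up to 0.57, is not excluded, and the arrays of day 2 were not part of this test. Scores from the brighter probes alone correlated at 0.996 with those from all probes, which include them. The axis thus did not need the dimmer probes, but how far these carry it too was not tested. At day 2 the later scan session scored a mean of 27.6 above the earlier one over the 2 soils together, with all 4 of its scores above the 4 of the earlier session, and jar and scan session cannot be told apart there, since each session held its own jars. No biological explanation was tested.

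Tests between days called 32 probes for day 4 minus day 2, 11 for day 7 minus day 2, 2 for day 7 minus day 4, and 19 by the F test. The differences were 5.35 and 6.69 for Fcc02721 at days 4 and 7 against day 2, 4.23 for Fcc00943C1, -3.25 and -2.38 for Fcc00583C1, -3.22 for Fcc00950, 4.53 for Fcc05669 and -1.32 for Fcc01171C1. Between days 4 and 7 they were 3.02 for Fcc00272 and 0.76 for Fcc02871C1. The reference RNA was not well above background for Fcc00583C1 at days 4 and 7 and for Fcc01171C1 at day 7, so the fitted ratios there are no exact sizes and the sizes of these differences are uncertain. For Fcc00950 at day 4 it was well above background on 1 of 4 arrays, which leaves the size of that difference uncertain too.

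If the arrays are taken as exchangeable, chance can be excluded at the 5% level for the difference between days 2 and 4, where 1 of 35 splits of the 8 arrays, the real one, gave as many as 32 calls and the highest other gave 0. It can also be excluded for days 2 and 7 (1 of 35 splits, 11 calls, highest other 1), for the F test (1 of 100 drawn splits, 19 calls, highest other 13) and for the average over the days (1 of 100 drawn sign patterns, 1392 calls, highest other 590). These splits ignore the scan sessions, in which arrays of day 2 correlated at 0.84 and 0.85, against 0.56 to 0.76 between its sessions. With scan session as a random block in limma, 1 probe was called between days 2 and 4, 0 between days 2 and 7 (228 at an unadjusted p under 0.05), 3 by the F test and 594 for the average. The fitted differences of the named probes from day 2 could not change under this block, given the balance of days and dyes within the sessions. Their adjusted p rose, and the lost calls neither show nor exclude a session effect. By the design, day 2 was scanned apart from the later days, and a difference between them cannot be told apart from a difference of scan session. Nor can a difference between any days be told apart from a difference of slides, since each day had its own. Chance cannot be excluded for days 4 and 7, where 3 of 35 splits gave 2 or more calls and the highest other gave 7. The single days have only 8 sign patterns of their 4 arrays, too few for a share under 0.05. At each of them 1 pattern, the real one, gave as many calls, with 684, 233 and 570 calls at days 2, 4 and 7 and 0, 0 and 2 for the highest other.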

How the results depend on the processing

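The coefficient for the scan sessions of day 2 and the random block on array number were chosen after seeing the data. The order of counts here is day 2, day 4, day 7, the average over the days, day 4 minus day 2, day 7 minus day 4, day 7 minus day 2 and the F test, with 684, 233, 570, 1392, 32, 2, 11 and 19 probes called. Counts within 1.5 times of these are not repeated. The cause of each shift was not tested unless stated.

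Agilent's processed signals gave 332 at day 2, 13 for day 4 minus day 2 and 0 for day 7 minus day 4 (289 at an unadjusted p under 0.05). A normexp offset of 10 gave 19 for day 4 minus day 2 and 1 for day 7 minus day 4. Median centring gave 130 at day 4, 1 for day 7 minus day 4 and 5 for day 7 minus day 2. Scaling between arrays gave 1 for day 7 minus day 4. The strict filter, which tests 2602 probes, gave 375 at day 2, 10 for day 4 minus day 2, 1 for day 7 minus day 4 and 9 by the F test. No dye coefficient gave 27 for day 7 minus day 2 and 36 by the F test. Fits of the compared days alone, with fewer arrays, gave 202, 66 and 89 at days 2, 4 and 7, 0 for day 7 minus day 4 (156 unadjusted) and 3 for day 7 minus day 2. Array weights, whose estimation stopped before converging, gave 570 at day 4, 1374 at day 7, 57 for day 4 minus day 2, 130 for day 7 minus day 4, 34 for day 7 minus day 2 and 124 by the F test. The trend and robust prior gave 1 for day 7 minus day 4, 27 for day 7 minus day 2 and 29 by the F test. The scan sessions of day 2 as a coefficient gave 60 for day 4 minus day 2, 46 for day 7 minus day 2 and 51 by the F test. Scan session as a random block (correlation 0.17) gave 424, 66 and 91 at days 2, 4 and 7, 594 for the average, 1 for day 4 minus day 2, 0 for day 7 minus day 2 (228 unadjusted) and 3 by the F test. An adjusted p under 0.01 left 288, 85, 132, 826, 4, 0, 3 and 0, with 219 and 372 unadjusted where it left 0.

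No background correction, no filter, saturated spots left out, slide as a random block (correlation 0.10) and the authors' value table kept every count within 1.5 times.

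The replicate number as a block, which leaves 5 residual degrees of freedom, gave 3 for day 4 minus day 2 and 0 for day 7 minus day 4, day 7 minus day 2 and the F test (170, 347 and 306 unadjusted). The numbers do not pair the arrays: deviations of same-numbered arrays correlated from -0.47 to 0.39, with 3 of 12 pairs above 0.1, and 1 of the 12 arrays was closest to an array of its own number. As a random block (correlation -0.07) the array number gave 23, 2, 9 and 16.

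Leaving out 1 array at a time gave 328 to 776 at day 2, 93 to 323 at day 4, 129 to 705 at day 7, 1134 to 1514 for the average, 2 to 39 for day 4 minus day 2, 0 to 4 for day 7 minus day 4, 0 to 35 for day 7 minus day 2 and 2 to 47 by the F test. The named probes kept their direction in all 626 recomputed values and missed the threshold in 91. The gene lists and their alternatives were not run, because the probes have no names. Dim signals limit the falls and rises of probes not well above background in 1 RNA.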

Other observations

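The test of cysteine-rich reading frames was chosen before its result was seen.

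Many cysteine-rich proteins bind metals, so a hypothesis was that cadmium raises transcripts with a cysteine-rich reading frame. Of the 3994 tested probes, 2992 had a forward frame without a stop codon over the 60 bases, and 22 had at least 4 cysteine codons in such a frame. Their mean change averaged over the days was 0.11, against 0.014 in probe sets of the same size matched on intensity. The difference of 0.096 lay within the spread of the matched means (SD 0.11, permutation p = 0.372, two-sided). The rule set beforehand counted such a p with a difference this small against the hypothesis. The difference plus its SD passed the limit of that rule, so a small rise of these 22 probes is not excluded. An open frame over 60 bases also does not show that a probe is coding. The true frame and strand of the probes are not known here, so the test cannot decide the hypothesis. Of the 22, 5 were called higher and 3 lower, a share of 36.4%, against 34.9% of all tested probes.

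Probe names ending in Rev, whose meaning the sources do not give, passed the filter less often than others, with 50 of 83 against 3944 of 5048 (Fisher's exact test, two-sided, p = 0.000263). Averaged over the days, 23 of those 50 probes were called, against 1369 of the 3944 others, a difference that was not tested. Among 12 pairs of tested probes that share a cluster number, 10 changed in the same direction, and both probes were called in 4 pairs, in the same direction in each. Their changes correlated at r = 0.17 across pairs (permutation p = 0.428, two-sided).

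Against the mean of the other 3 arrays of the day, slopes of rises lay between 0.32 and 1.25 over the 12 arrays, with the lowest on day 7 array 4 and the next at 0.76. Slopes of falls lay between 0.34 and 1.47. The difference between rises and falls was not tested.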
